A study of Homo sapiens with 6 samples.

How the data were processed

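RNA of TCP1 cells, labelled as a papillary thyroid carcinoma line, was measured on 6 arrays of 2 colours. Each array set cells given a miR-129-5p precursor against cells given a negative control precursor. The design text names 3 independent experiments in dye swap. Per the labels, the replicate numbers and extract names put the same 2 RNA extracts on the 2 arrays of each experiment, once with miR-129-5p in Cy3 and once in Cy5. An experiment was therefore 1 replicate, and its 2 arrays were averaged before any test, so n = 3. The numbers pair the arrays through these shared extracts.

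The deposited values are log ratios, taken here as log2, of 27648 rows on each of the 6 arrays, with 0 missing values. The authors' scanner, background correction and normalization within arrays are not given in the sources used here. The mean of every array was 0, and the array medians lay between -0.025 and 0.028, so each array had been centred on its mean. The log base was not stated. A base of 10 would make the largest ratios implausibly large, while a base of 2 or e stays open, so every fold below holds only if the base is 2. Array values carry no spot intensities, so dim and saturated spots could not be told from others. With the background correction not given, how the ratios of dim spots were affected is not known. Centring on the mean hides any change shared by all transcripts.

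The 2 arrays of each experiment correlated at 0.73, 0.77 and 0.64 over all rows although their dyes were exchanged. The deposited table had therefore already been turned to 1 direction per experiment, and no sign was altered here. The number on top of the ratio is not stated. It is taken as miR-129-5p, an assumption that is not settled. The design text and the descriptions of the arrays with miR-129-5p in Cy3 name it first. Values of the other arrays carry a median of 9 decimals against 6, as if recomputed. If so, the common custom of Cy5 over Cy3 would put the negative precursor on top of the arrays with miR-129-5p in Cy3. That custom goes against this choice. No gene was used to choose the direction. Arrays of experiments 1 and 2 with the same dyes correlated at -0.35 with miR-129-5p in Cy3 and at -0.33 with it in Cy5. For that reason counts are also given with the sign of each experiment turned.

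Rows were named through the platform annotation: 17711 rows had 1 gene symbol, 0 had several and 9937 were unnamed. Symbols were updated with the RefSeq gene table of GRCh38.p14, by accession for 14721 rows, by current symbol for 1806 and by a unique synonym for 1029, while 155 kept the old symbol. No coordinates are given because the array annotation names no genome build. The 321 ACTB and 272 GAPDH rows, printed as repeated controls, were left out. The remaining 17118 rows were averaged to 14545 genes, of which 2055 had several rows.

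The test was limma 3.58.1 in R 4.3.3: a moderated, two-sided test of the 3 experiment means against 0, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. A total of 32 gene lists fixed from textbook knowledge was tested with camera at a preset correlation of 0.01. Beside it stand camera with an estimated correlation and fry, which asks whether the genes of a list move on balance 1 way. The lists covered reported miR-129-5p targets, histone deacetylases and acetyltransferases, apoptosis, the cell cycle, thyroid, epithelial and mesenchymal genes, signalling, stress and metabolic pathways, and markers of 4 other cell types. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.

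The test was run first on simulated ratios of 14545 genes with the real spreads, of which 50 each were changed by 0.5, 1, 2 and 3. It called 0% of the genes changed by 0.5 or by 1, 50% of those changed by 2 and 68% of those changed by 3, with 2 unchanged genes called. Those spreads included the opposed difference of experiments 1 and 2 as variance. In a second simulation, which carried that difference itself and drew its noise otherwise, it called 0%, 0%, 30% and 56%, with 0 unchanged genes called. There the fit with a term opposing these experiments called 0%, 76%, 98% and 100%, with 3. The noise of these simulated data was drawn from that same fit, and their opposed difference had the form of its term. Its recovery was therefore favoured in advance and does not measure its power on the real data. In the first simulation the fit with this term called 0% at each size. In that simulation the fit of all 6 arrays with the replicate block called 0%, 50%, 82% and 86% and also 57 unchanged genes. Its calls there included more false ones than its threshold names. This fit was not run on the simulated data with the opposed difference. Of 5 simulated lists shifted by 0.5, camera with the preset correlation called 5 and camera with an estimated correlation called 0, and neither called any of 15 unshifted lists.

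Alternatives fixed before the data were examined covered scaling between arrays, the 6-array fit with the replicate block, each dye orientation alone, leaving out each experiment, the moderation of the variance, thresholds, the averaging of rows and a filter on genes whose swapped arrays differed most. A term opposing experiments 1 and 2, turned signs, fry with the block and the block fit without each experiment were added after the data were seen. A list test with the block had been planned with camera, which takes no block, so fry took its place. The rule for named genes was to take the 12 highest and 12 lowest genes past the threshold with the same sign on all 6 arrays. If none passed, it took the 10 with the smallest p, given as values. It also took every reported target and the 2 members of each other list with the smallest p. Because none passed, the first part was also applied to the block fit, a step decided after that result. The planned test of miR-129-5p seed sites was not run, since no transcript sequences were used here.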

Results

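TCP1 cells were transfected with a precursor of miR-129-5p, a microRNA that lowers transcripts carrying matches to its seed, or with a negative control precursor. Their RNA was compared on 6 arrays, 2 dye-swapped arrays in each of 3 independent experiments, which gave log ratios of 14545 genes with n = 3. The number of arrays limits the precision. Ratios are given as miR-129-5p over the negative precursor. This direction is assumed and not settled, and turning the whole table would turn every sign below. The log base was taken as 2.

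The comparison asked which transcripts differed when miR-129-5p was raised. EMP1, an epithelial membrane protein, had the lowest mean log ratio, -3.71 ± 0.31 (SD, n = 3), or 13.1-fold lower if the base is 2. VPS26A, a subunit of the retromer that sorts endosomal cargo, stood at -2.27 ± 0.10. LBR, the lamin B receptor of the inner nuclear membrane, stood at -1.75 ± 0.13, and CCNA1, cyclin A1, at -1.80 ± 0.16. GALNT1, which starts mucin-type O-glycosylation, stood at -1.52 ± 0.11. The values of CKAP4, an endoplasmic reticulum membrane protein, and SH3KBP1, an adaptor in receptor endocytosis, were -1.35 ± 0.06 and -1.32 ± 0.06. On the other side, RBM24, an RNA-binding protein, had 2.39 ± 0.34, FAM216A 1.76 ± 0.24 and KRT34, a hair keratin, 1.62 ± 0.13. These 10 genes had the smallest p-values, and each had the same sign on all 6 arrays.

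None of them passed the test. limma called 0 of 14545 genes on the 3 experiment means, 0 higher and 0 lower, and the smallest adjusted p was 0.288. At an unadjusted p under 0.05 there were 848 genes, 458 higher and 390 lower, where 727 would be counted with no change at all. This count was 1399, 1370 and 182 without experiments 1, 2 and 3, and 1379, 1412 and 24 with their signs turned, so its excess over 727 is no evidence of a shared change. In simulated data of this size with the real spreads, the test found 0% of the genes changed by 1 and 50% of those changed by 2. It found 0% and 30% in the second simulation, which carried the opposed difference of experiments 1 and 2 and had other noise. Changes of that size may therefore have gone uncalled with 3 experiments.

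A fit of all 6 arrays with a dye term and the replicate block called 73 genes, 20 higher and 53 lower, with a smallest limma adjusted p of 0.0019. Its lowest ratio was that of EMP1. SLPI, a secreted protease inhibitor, had -2.90 ± 1.04, and MMP1, the interstitial collagenase, had -2.61 ± 1.06. IL13RA2, a decoy cytokine receptor, had -2.55 ± 0.60, and CA12, a membrane carbonic anhydrase, had -1.98 ± 0.78. NPEPPS, a cytosolic aminopeptidase, had -2.55 ± 0.57. CHST1, a sulfotransferase, had -2.27 ± 0.85, and ATOH8, a transcription factor, had -2.17 ± 0.58. ZMAT2, a zinc finger protein, had -2.11 ± 0.53, and NDRG1, a stress-responsive gene, had -1.78 ± 0.75. VPS26A and CCNA1 completed the lowest 12.

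The highest 12 in that fit held RBM24, FAM216A and KRT34 and 9 further genes. KRTAP2-1, a keratin-associated protein, had 2.24 ± 0.52, and KRT81, a hair keratin, had 2.03 ± 0.37. THBS1, thrombospondin of the extracellular matrix, had 2.00 ± 0.63, and SDC2, a syndecan, had 1.90 ± 0.54. SLC7A5, a large neutral amino acid transporter, had 1.86 ± 0.59, and GFRA1, a receptor of the GDNF family, had 1.80 ± 0.34. TAGLN3, a transgelin, had 2.14 ± 0.66, and ZBED2, a transcription factor, had 2.01 ± 0.69. MCAM, a cell adhesion molecule, had 1.41 ± 0.52 over 3 rows, of which 2 stood at 2.05 and 2.13 and 1 at 0.05. All errors are SDs over the 3 experiments. The block fit called 152 genes without experiment 1, and 0 without experiment 2 or without experiment 3. In simulated data with the real spreads, which held the opposed difference of experiments 1 and 2 only as variance, it also called 57 unchanged genes. In those data it found 50%, 82% and 86% of the genes changed by 1, 2 and 3. It was not run on the simulated data that carried that difference itself. On the real ratios with the sign of experiment 1, 2 or 3 turned, it called 12, 0 and 0 genes.

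**Figure D1:**
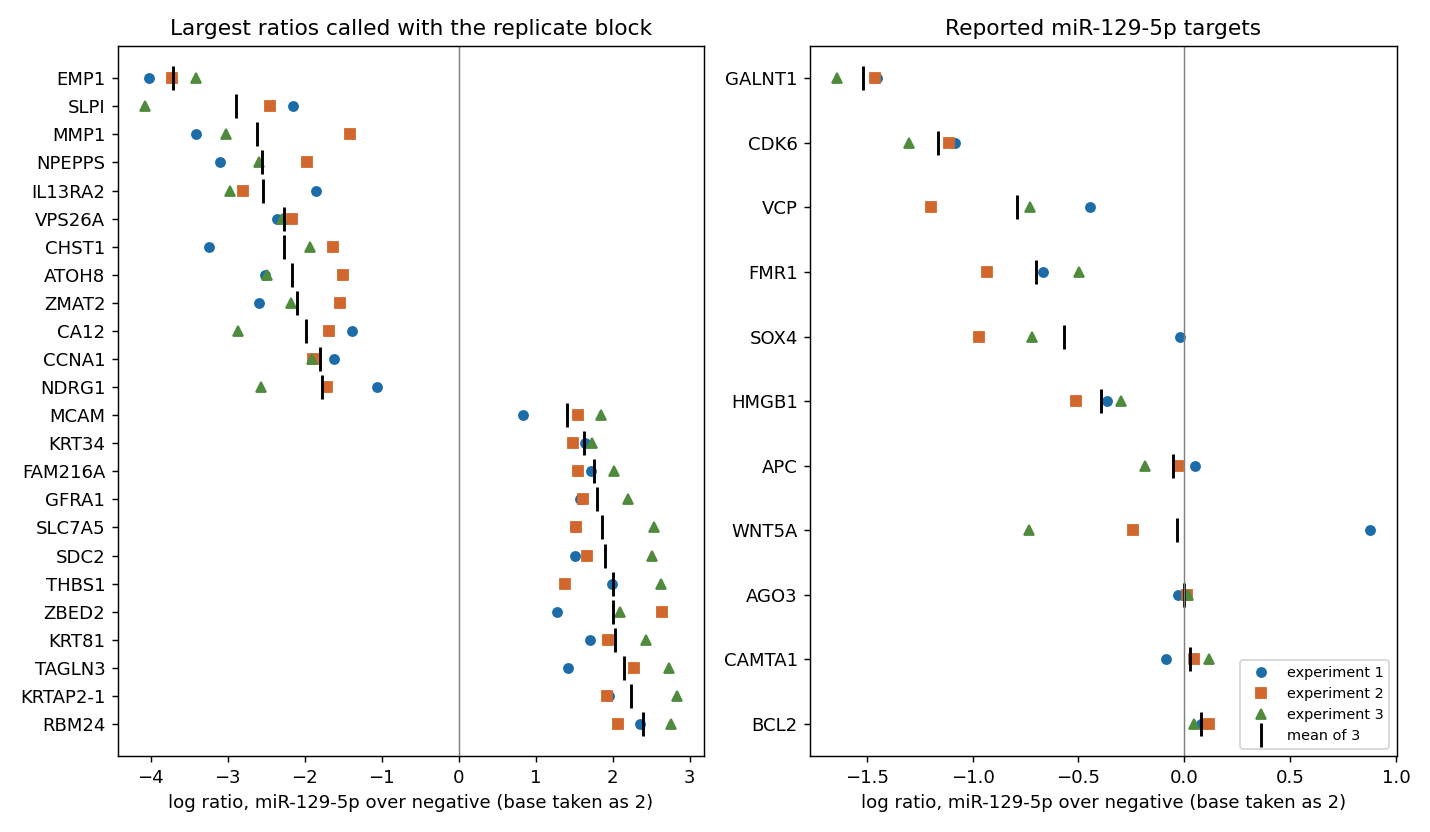
Log ratios (horizontal axis, base taken as 2) of the 24 genes with the lowest and highest means among the 73 genes called with the replicate block, left, and of the 11 reported miR-129-5p targets, right. Symbols are the 3 experiments and bars their mean; EMP1 lies lowest at -3.71, and GALNT1 and CDK6 lie lowest among the targets at -1.52 and -1.16.

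The reported targets of miR-129-5p, taken from general knowledge of the microRNA, were lower as a group by camera, a call that an estimated correlation did not keep. Of the 11 listed genes, all measured, 9 had a mean below 0, 6 of them in all 3 experiments, and the median was -0.39. The median was -0.13 with 1 row per gene and -0.22 without the genes whose swapped arrays differed most, and camera called the list in both (adjusted p = 0.0026 and 0.0017). GALNT1 (-1.52 ± 0.11) and CDK6, a kinase of the G1 phase (-1.16 ± 0.12), had the lowest means and were the 2 targets called in the block fit. VCP, an ATPase that extracts ubiquitinated proteins, stood at -0.79 ± 0.38. FMR1, an RNA-binding translational regulator, stood at -0.70 ± 0.22, and HMGB1, a chromatin protein, at -0.39 ± 0.11. These 5 genes passed limma's test adjusted over the list alone, and 0 passed over all genes. SOX4, a transcription factor, had -0.57 ± 0.49 with experiment 1 at -0.02. The means of APC (-0.06), WNT5A (-0.03), AGO3 (0.00), CAMTA1 (0.03) and BCL2 (0.08) lay near 0. WNT5A ranged from -0.73 to 0.88 across experiments.

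camera called the target list at an adjusted p of 4.2e-05. With an estimated correlation the call was lost (adjusted p = 0.90 with an estimated correlation), and fry gave an adjusted p of 0.384, or 0.0397 with the replicate block. The correlation estimated within this list was -0.017, below the preset 0.01. Of 5 simulated lists that were shifted, camera with an estimated correlation called 0. Its loss of a call, here and for the lists below, therefore cannot tell whether a list shifted. The medians were -0.09, -0.51 and -0.50 in experiments 1, 2 and 3, and leaving out each in turn kept the camera call, with adjusted p between 6.3e-05 and 0.023. With the sign of experiment 1, 2 or 3 turned the camera call was lost, with adjusted p of 0.257, 0.928 and 0.482. A shift below 0 in every experiment shrinks when 1 sign is turned, so this loss does not test how robust the call is. Among targets with several rows, those of CDK6 and HMGB1 differed most. CDK6 had 1 row at -2.20 and 1 at -0.13, and HMGB1 had 1 row at -1.69 and 4 between -0.16 and 0.02. Rows of APC (-0.17 and 0.05), BCL2 (between -0.12 and 0.28) and CAMTA1 (between -0.05 and 0.09) lay on both sides of 0. GALNT1, CDK6 and VCP also stood in the lists of O-glycosylation, G1/S and proteasome genes.

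Genes of G2/M and mitosis were lower on average, through experiment 2. Of 30 measured members 29 had a mean below 0, and the median was -0.44 (camera adjusted p = 4.1e-08). The call was lost with an estimated correlation, here 0.50 (adjusted p = 0.90 with an estimated correlation). The medians were 0.09, -1.22 and -0.19 in experiments 1, 2 and 3. CDC25B, a phosphatase that activates cyclin-dependent kinases, had -1.14 ± 0.19, and MKI67, the Ki-67 proliferation antigen, had -0.81 ± 0.15, each below 0 in all 3 experiments. These 2 genes passed adjusted over the list alone and 0 over all genes. The list was not called in fry with the replicate block (adjusted p = 0.613) or by camera without experiment 2 (median -0.11, adjusted p = 0.441). At the preset correlation camera kept the call without experiment 1 (median -0.73, adjusted p = 2.8e-09) and without experiment 3 (median -0.62, adjusted p = 1.2e-13). It also kept it with a term opposing experiments 1 and 2 (adjusted p = 5.2e-11).

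NF-kB and inflammatory genes were lower on average, through experiment 3. The median of 22 genes was -0.77, 16 had a mean below 0, and camera gave an adjusted p of 0.032. The call was lost with an estimated correlation, here 0.46 (adjusted p = 0.90 with an estimated correlation). The medians were 0.32, -0.30 and -2.01 in the 3 experiments. NFKBIA, an inhibitor of NF-kB and also its target, had -1.20 ± 0.84, and IL1B, an inflammatory cytokine, had -1.37 ± 1.09. No member passed over all genes or adjusted over the list alone. The list was not called in fry with the replicate block (adjusted p = 0.691) or by camera without experiment 3 (median -0.02, adjusted p = 0.481). At the preset correlation camera kept the call without experiment 1 (median -1.34, adjusted p = 1.6e-05) and without experiment 2 (median -0.28, adjusted p = 0.035). The call was also lost on the arrays with miR-129-5p in Cy5 alone (median -0.57, adjusted p = 0.187), without the genes whose swapped arrays differed most (median -0.83, adjusted p = 0.119) and with a term opposing experiments 1 and 2 (median -0.77, adjusted p = 0.119).

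**Figure D2:**
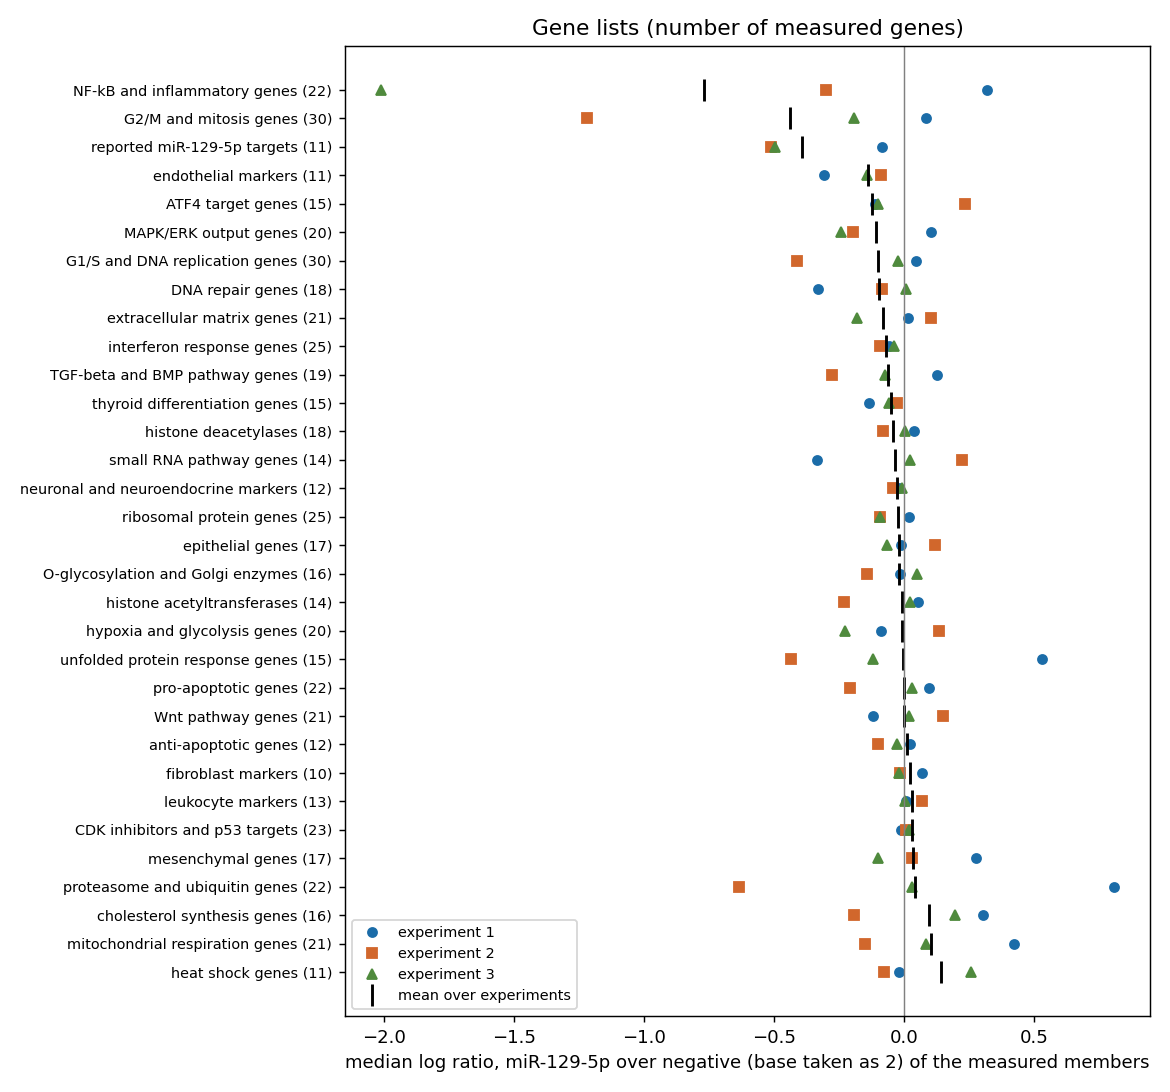
Median log ratio (horizontal axis, base taken as 2) of the measured members of each of the 32 gene lists, with the number of genes in brackets; symbols are the 3 experiments and bars the median of the genes' means over experiments. The targets lie below 0 in every experiment, whereas G2/M genes stand apart in experiment 2 (-1.22) and inflammatory genes in experiment 3 (-2.01).

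None of the other 29 lists was called, with medians between -0.14 and 0.14 and camera adjusted p between 0.116 and 1.00. Histone deacetylases, 18 genes, had a median of -0.04, and HDAC1 had 0.60 ± 0.42. Among pro-apoptotic genes, with a median of 0.00, BAD stood at -0.85 ± 0.16 and passed adjusted over the list alone, while TNFRSF10B, a death receptor, stood at 1.05 ± 0.50. Anti-apoptotic genes had a median of 0.01. Of the cyclin-dependent kinase inhibitors and p53 targets, CDKN1C stood at -1.25 ± 0.17 and passed adjusted over the list alone, while CDKN1A, the inhibitor p21, stood at 0.63 ± 0.17. CDKN1C and SLC7A5 were called in the block fit. SLC7A5 was also the ATF4 target that passed adjusted over the list alone. The thyroid differentiation list had a median of -0.05 and the epithelial list -0.02, with EPCAM at 0.48 ± 0.24.

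Markers of other cell types gave no call. The medians were 0.03 for leukocyte, -0.14 for endothelial, 0.02 for fibroblast and -0.03 for neuronal and neuroendocrine markers, with camera adjusted p of 0.813, 0.116, 0.735 and 0.813. The repeated control rows of ACTB averaged between -0.11 and 0.12 per array, and those of GAPDH between -0.13 and 0.13.

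The 2 arrays of each experiment ran together, while experiments 1 and 2 ran against each other. Over the 14545 genes, which are not independent replicates, the swapped arrays correlated at 0.79, 0.83 and 0.73. Experiments 1 and 2 correlated at -0.46, experiments 1 and 3 at 0.32 and experiments 2 and 3 at 0.38. The same sign in all 3 experiments was seen for 3428 genes, or 23.6%, where 25% would be counted for unrelated experiments. EMP1 stood at -4.02, -3.72 and -3.41 in experiments 1, 2 and 3. With the sign of experiment 1, 2 or 3 turned, limma again called 0 genes on the experiment means, and the block fit called 12, 0 and 0.

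**Figure D3:**
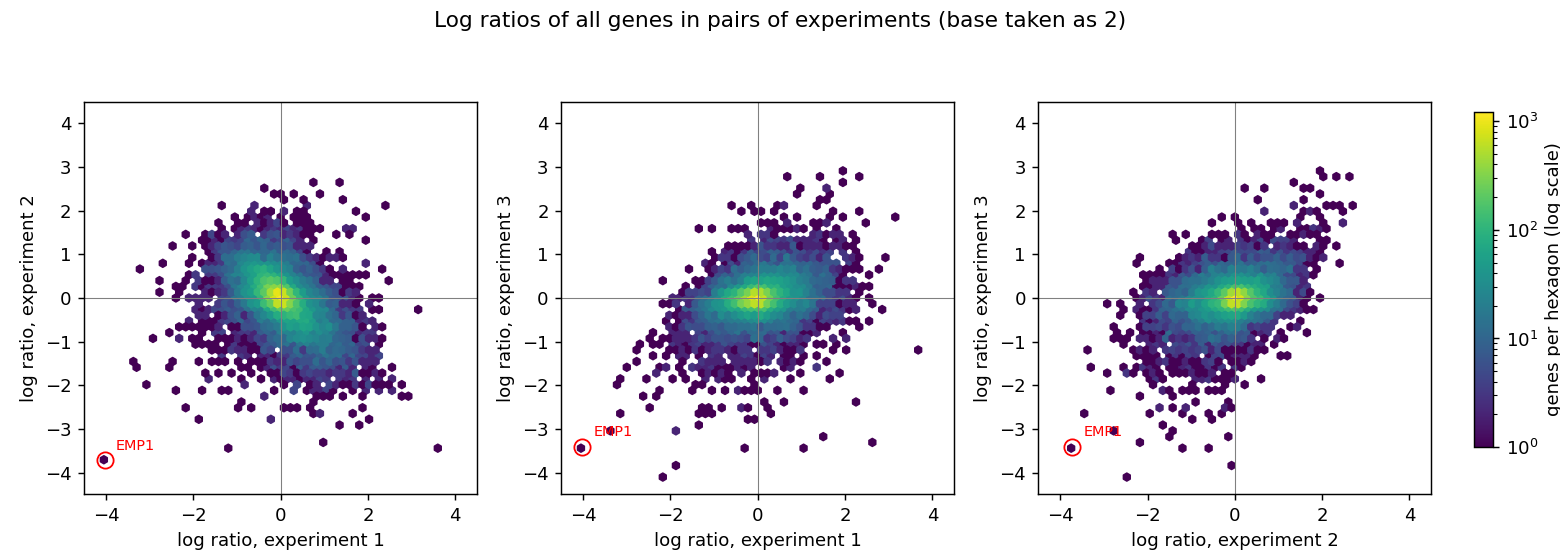
Log ratios of the 14545 genes in pairs of experiments (both axes, base taken as 2), with the number of genes per hexagon in colour on a log scale. Experiments 1 and 2, left, run against each other (r = -0.46), the other pairs run together (0.32 and 0.38), and EMP1, circled, is low in all 3.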

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

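All explanations in this part were tested only after the result was seen. The dye differences below come from a limma test separate from the planned fit with the replicate block.

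Between the 2 dye orientations, 815 genes differed in that test. Of these, 429 had a higher ratio when miR-129-5p was in Cy3 and 386 a lower one. The swapped arrays hold the same RNA, so no biological explanation was tested. Gene-specific dye bias is a candidate explanation: it predicts the same difference in each experiment, and the difference correlated over genes at 0.47 to 0.56 between experiments. Such a bias cancels in the mean of the swapped arrays.

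Among the 9937 rows with no gene name, which the comparisons did not use, 68 had the same sign on all 6 arrays and a mean of at least 1 in size, 33 higher and 35 lower. By the same rule 181 of the 14545 named genes, averaged over their rows, passed. Tested singly with limma, 0 unnamed rows passed the threshold. Of the 9937 rows, 395 had an unadjusted p under 0.05, fewer than would be counted with no change at all.

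The opposed ratios of experiments 1 and 2 were the broadest pattern in the data. A turned ratio or a complete exchange of samples in 1 experiment is argued against as the whole cause, because no turn of signs can make all pairs of experiments correlate above 0 when the product of their 3 correlations, -0.056, is negative. A slide or print artefact is argued against by the difference between these experiments, which correlated at 0.926 between the separate arrays of the 2 dye orientations. An exchange of the control extracts, or of the miR-129-5p extracts, between experiments 1 and 2 stays open. It predicts that their ratios, each minus experiment 3, oppose on a slope near -1; the slope was -0.867, but their correlation of -0.43 was weaker than the bound of -0.5 set for it. A culture state that differed between dishes stays open too. The opposed axis held 88.2% of the variance between experiments. Unrelated experiments would give about 50% only with equal spreads, and the SDs here were 0.56, 0.54 and 0.40. The share also follows from these SDs and from the correlations that raised the question, so it cannot tell a culture state from other causes. An exchange of extracts between experiments 1 and 2 would leave the mean of the 3 experiments as it is.

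The 73 genes of the block fit compare with at most 12 when the sign of 1 experiment is turned, and 1 of 4 sign patterns gave as many. The test on experiment means gave 0 genes in all 4 patterns, with 0 as the highest of the others. With 4 patterns a share under 0.05 cannot be reached.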

How the results depend on the processing

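Chosen after the data were seen were the term opposing experiments 1 and 2, the turned signs, fry with the block and the block fit without each experiment. The count of 0 changed genes held with arrays centred on the median, quantile-normalized or scaled, in each dye orientation alone, without each experiment, with robust moderation, at an adjusted p of 0.1, with a minimum ratio, with 1 row per gene, with rows tested singly, without the noisiest 25% of genes and with turned signs. It moved to 73 genes (20 higher, 53 lower) with the replicate block, to 257 (118 higher, 139 lower) with 6 arrays as if independent, to 119 (33 higher, 86 lower) with the term opposing experiments 1 and 2, which leaves 1 residual degree of freedom per gene and of whose calls 43 were shared with the block fit, and to 1 (1 higher) with a plain one-sample test, SRPRB at 0.84. The block fit without each experiment gave 0 to 152 genes. The 3 called lists became 0 with an estimated correlation, 0 with fry, 1 with fry and the replicate block, 4 to 5 without each experiment, 5, 4 and 6 with the sign of experiment 1, 2 or 3 turned, 4 with miR-129-5p in Cy3 alone, and 2 with it in Cy5 alone, without the noisiest genes or with the opposing term. The agreement of swapped arrays, a mean r of 0.783, was 0.716 for rows tested singly. For these the cause was not tested, except that treating swapped arrays as independent counts each extract pair as 2 replicates. List medians that reversed included G2/M (0.35, sign of experiment 2 turned). With the sign of experiment 3 turned they were NF-kB (0.40), unfolded protein response (0.11) and hypoxia (0.15). The proteasome list reversed to -0.39 without experiment 1 and to -0.51 with the sign of experiment 1 turned, and kept its side at 0.31 without experiment 2. The unfolded protein response, hypoxia and proteasome lists had main medians near 0 (-0.004, -0.009 and 0.04) and no call there. Over all 32 lists and their settings, the other values kept their side in 366 cases, gained a call in 14, lost it in 9 and moved in 83. Of 93 single genes followed, 93 values across settings passed the threshold and 57 moved. In the either-direction test of fry, the block added a call of extracellular matrix genes (adjusted p 0.827 without it, 0.0498 with it). Restricting to genes measured on all 6 arrays gives no separate value, since none was missing, and seed sites were not run. Signal over background is not known from ratios.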

Other observations

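The test on the difference of experiments 1 and 2 was chosen after the values were seen.

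The medians of 2 lists, picked after their values were seen, had opposite signs in experiments 1 and 2, though not every member did. The medians of most of the 32 lists had opposite signs too, and over all genes these experiments correlated at -0.46. The proteasome and ubiquitin list, 22 genes, had medians of 0.81, -0.64 and 0.03 in experiments 1, 2 and 3, and 19 members were higher in experiment 1 than in experiment 2. The unfolded protein response list, 15 genes, had medians of 0.53, -0.44 and -0.12, with 13 members higher in experiment 1. On the difference of these experiments camera gave adjusted p of 8.4e-06 for the proteasome list, 0.0019 for the unfolded protein response and 8.4e-06 for G2/M genes. In the fit of the mean over experiments, the estimated correlations within these lists were 0.45, 0.49 and 0.50, far above the preset 0.01. The residuals of that fit hold the difference of experiments 1 and 2, and no correlation was estimated in the fit of the difference. These camera p-values may therefore be too small. On the mean over experiments the first 2 lists had medians of 0.04 and 0.00.

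In the test of change in either direction, which does not ask that members oppose each other, fry gave adjusted p of 0.025 for cyclin-dependent kinase inhibitors and p53 targets. It gave 0.023 for O-glycosylation and Golgi enzymes and 0.023 for the reported targets. In each of the first 2 lists 1 member passed adjusted over the list alone, CDKN1C at -1.25 and GALNT1 at -1.52.

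Of 20 genes called higher in the block fit, 3 were keratin or keratin-associated genes, KRT34, KRT81 and KRTAP2-1, out of 99 such genes measured, a family picked after it was seen and not tested. Close relatives differed: KRT86 stood at 0.34 ± 0.52, KRT83 at 0.01 ± 0.15, KRT33B at 0.57 ± 0.39 and KRT33A at -0.15 ± 0.23. The simple epithelial keratins KRT8 and KRT18 stood at -0.08 ± 0.84 and -0.34 ± 0.20.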
